A study of Mus musculus with 2 samples.

How the data were processed

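The 2 libraries of poly(A)-selected RNA from whole kidney of 8-week-old male mice formed 1 group. Each library had a gene table and a transcript table. Per the deposited notes, reads were aligned to mm10, and genes and transcripts of the GENCODE M4 annotation were quantified for each library from alignments to the transcriptome. The aligner and the quantifier are not given in the sources used here. The deposited expected counts are the authors' estimates of the reads of each gene or transcript, with reads that match several divided among them, so they need not be whole. The deposited TPM values are scaled by effective length and to the same sum over all rows of a library, and the authors' files also hold a posterior mean TPM. The deposited FPKM values are scaled by effective length and depth. The percent of a gene's TPM held by each transcript is the authors' value, per the file headers. The effective length was the length minus 35 in rows longer than 100 bases. The labels name an RNA size range above 200 and spike-in RNA.

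Each gene table had 69691 rows. Of these, 43346 were genes, 26248 were tRNA annotations, 96 were ERCC spike-in sequences and 1 was the phiX genome. Gene rows held 99.98% and 99.97% of the expected counts in replicates 1 and 2. Comparisons used the gene rows. Symbols, biotypes and coordinates came from GENCODE M21 on the same assembly, matched on the gene identifier without its version, and its gene models can differ from those used for quantification. A symbol was found for 42462 gene rows. The 884 rows without one stayed in library sizes and counts of genes and were not named. They held 4.79% and 5.63% of TPM, of which a single row held 4.27% and 5.09%.

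Total expected counts were 17011127 in replicate 1 and 15057997 in replicate 2, and TMM effective library sizes were 16244328 and 15711346. Intervals of shares are 95% Wilson intervals, and a count of 0 is given the limit of 3 counts. The labels give the libraries the same donor identifier and separate biosamples, so SDs measure the spread between these libraries, which may be technical. The p-values of the exact binomial test hold counting error only and do not measure that spread. Comparing the counts over genes showed that the tables were not of the same library.

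Expected counts were rounded to whole numbers for tests. Genes with at least 10 counts on average were tested with a 2-sided exact binomial test of the counts of each gene given their sum, with library sizes scaled by TMM from edgeR, and Benjamini-Hochberg adjustment. A gene was said to differ at an adjusted p under 0.05 and a log2 ratio of at least 1 in size. Log2 ratios of single genes in this test add 0.5 to each count. The common biological coefficient of variation came from edgeR's estimateDisp with an intercept alone. Differences between lists and pairs used log2(TPM + 1), which understates the change of low genes. Before the data were examined, 37 gene lists with 309 genes, 24 gene pairs and 24 genes for transcript comparison were fixed, together with the tests and the alternatives, except those named as added. A list's median log2 ratio was placed among 10000 random lists of the same size drawn from nuclear protein-coding genes in 20 bins of mean expression, and a list stood apart below percentile 2.5 or above 97.5. A pair differed when its mean log2 ratio exceeded 3 times the pooled SD of such ratios.

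The rule for named genes, also fixed beforehand, took the 25 nuclear protein-coding genes of highest mean TPM, up to 4 members of each list and any member of lists of sex-linked, clock or immediate early genes or of lists that stood apart, the 10 largest ratios in each direction among differing genes at mean TPM of at least 5, the 6 largest and 6 smallest pair differences, and genes whose leading transcript differed with up to 6 others. Fewer were named where a group is summarised. Protein-coding genes among those that differed, and single genes in the closing section outside these lists, were chosen after their values were seen.

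Alternatives were DESeq2's size factors or total counts in place of TMM, other filters on low counts and low TPM, another pseudocount of 0.1, FPKM or expected counts in place of TPM, posterior mean TPM, other thresholds of the ratio, edgeR's exactTest with a fixed biological coefficient of variation of 0.1, and each library alone. Restriction to nuclear protein-coding genes, random lists from all genes, removal of a fit on GC content and transcript length, removal of shared list members, and another pooled SD for pairs were added after the data were examined. Leaving out 1 library leaves 1, for which no counting test is possible. GC content and length came from the longest M21 transcript of each gene.

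The counting test was tested on simulated libraries with the real means and sizes. Among 15237 genes it recovered 68.0% of 100 genes changed 2-fold and 90.0% of 100 genes changed 4-fold at an adjusted p under the threshold. Of the unchanged genes, 1 passed both criteria and 5 passed at any ratio. In the real libraries 3004 genes passed at any ratio, so the simulated libraries held less spread. They give no rate of false calls for libraries that spread as the real ones do. Simulated biological coefficients of variation of 0.05, 0.1 and 0.2 were estimated as 0.0496, 0.0994 and 0.199. Of 100 random lists of 10 genes, 7.00% fell outside the central 95%, and 100% of lists shifted by 0.4 were found. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. No read alignments or signal tracks were used here.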

Results

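Poly(A)-selected RNA of whole kidney was sequenced from 8-week-old male mice of strain B6NCrl. The labels describe 1 group of 2 libraries, biological replicates 1 and 2, each made from the pair of kidneys of an individual mouse. The labels give the libraries separate biosamples but the same donor identifier, so they do not settle whether the kidneys came from different animals, and the spread between the libraries may be in part technical. The gene table held 17011127 estimated reads in replicate 1 and 15057997 in replicate 2, and a TPM of 1 stood for about 36.0 and 30.7 reads of a nuclear protein-coding gene of median length. With 1 group there was no comparison between conditions. The design implied a description of which genes, nephron segments and cell types were represented in adult kidney RNA, and of how far the libraries differed. No permutation of the labels of 2 libraries can give a p below 0.5, so levels are given as mean TPM ± SD over the libraries, with n = 2 throughout. Coordinates are those of mm10, from the GENCODE M21 annotation of the same assembly.

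Kidney RNA was led by Kap, the androgen-regulated protein of proximal tubule cells, at 66537 TPM ± 2221 (SD, n = 2). Kap lies on chromosome 6 at 133849851 to 133853762 and took 3.62% of the gene reads of replicate 1 (95% Wilson interval 3.61% to 3.63%) and 3.71% of those of replicate 2 (3.70% to 3.72%). These intervals cover counting error only. Gpx3, the secreted glutathione peroxidase made by the kidney, followed at 12062 TPM ± 269 (chromosome 11, 54902453 to 54910377), and the ferritin heavy chain gene Fth1 reached 5169 TPM ± 141 (chromosome 19, 9980598 to 9985098). Mitochondrially encoded genes, rRNA and tRNA genes included, took 25.7% of gene reads in replicate 1 (25.7% to 25.7%) and 21.7% in replicate 2 (21.6% to 21.7%). All 13 mitochondrial protein genes were far above most nuclear genes, from mt-Nd5 at 6444 TPM ± 927 to mt-Co2 at 38889 TPM ± 6231.

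Among the 25 nuclear protein-coding genes with the highest mean TPM, several belonged to proximal tubule metabolism. Aldob, the fructose-bisphosphate aldolase of fructose breakdown and gluconeogenesis, stood at 2374 TPM ± 151 and Akr1a1, an aldehyde reductase, at 1851 TPM ± 267. Miox, the first enzyme of inositol breakdown, stood at 1207 TPM ± 158, the fatty acid transporter and acyl-CoA synthetase Slc27a2 at 1067 TPM ± 91.1, and Acsm2, a medium-chain acyl-CoA synthetase, at 1065 TPM ± 19.3. Ion handling was represented by Fxyd2, the regulatory gamma subunit of the sodium pump, at 2312 TPM ± 90.2, and by its catalytic subunit Atp1a1 at 1197 TPM ± 127. Atp5b, Ndufa4, Cox8a, Cox7b and Usmg5, all nuclear genes of oxidative phosphorylation, lay between 1054 TPM ± 114 for Cox7b and 1816 TPM ± 131 for Atp5b. The remaining genes among the 25 were Lars2, Tpt1, Klk1, Ftl1, S100g, Eef1a1, Spink1, Hba-a2, Gpx1 and Keg1. Fth1, Ftl1, Tpt1 and Eef1a1 have many processed copies, and their estimates are uncertain to the extent that reads were divided among these.

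The S1 and S2 list of the proximal tubule had the highest median of the epithelial lists. All 12 genes of this list were at TPM 1 or more in both libraries, with a median of 119 TPM ± 0.969. They included the phosphate transporter Slc34a1 at 877 TPM ± 108 (chromosome 13), the organic anion transporter Slc22a6 at 158 TPM ± 5.46, the glucose transporter Slc5a2 at 139 TPM ± 16.5 and the endocytic receptor Lrp2 at 115 TPM ± 2.96. The 6 genes of the S3 segment had a median of 52.9 TPM ± 3.13, led by Slc7a13 at 187 TPM ± 2.20 and the steroid hydroxylase Cyp7b1 at 97.6 TPM ± 21.8. On the log2(TPM + 1) scale, the median of the S1 and S2 list exceeded that of the thick ascending limb list by 2.54 ± 0.35 (SD, n = 2), a 5.83-fold difference, and that of the collecting duct principal cell list by 3.47 ± 0.06, an 11.1-fold difference. Both differences were larger than 3 times their SD. This SD measures the agreement of the libraries, not the choice of genes in each list, and no test was made.

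Each of the later segments was detected. In the thick ascending limb list, 9 of 10 genes were at TPM 1 or more in both libraries. Umod, which encodes uromodulin, stood at 375 TPM ± 96.0, the furosemide-sensitive cotransporter Slc12a1 at 102 TPM ± 33.4, and Egf at 99.7 TPM ± 23.3. Thin limb genes were lower, at a median of 2.36 TPM ± 1.43, with the chloride channel gene Clcnka at 15.4 TPM ± 7.19 and the urea transporter gene Slc14a2 at 2.36 TPM ± 1.43. In the distal convoluted tubule list Slc12a3, the thiazide-sensitive cotransporter, stood at 70.2 TPM ± 11.8 and the calcium-binding Pvalb at 15.9 TPM ± 0.177. The connecting tubule list included Klk1, tissue kallikrein, at 1711 TPM ± 33.5, S100g, a small calcium-binding protein, at 1528 TPM ± 95.7 and Calb1 at 78.8 TPM ± 5.11. All 11 principal cell genes were detected, among them the vasopressin-regulated water channel Aqp2 at 92.7 TPM ± 10.2, Aqp3 at 73.1 TPM ± 7.64 and Hsd11b2, which inactivates glucocorticoid, at 57.8 TPM ± 5.88. All 10 intercalated cell genes were detected too, with Atp6v1g3 at 23.6 TPM ± 0.948, the anion exchanger Slc4a1 at 5.33 TPM ± 1.82 and pendrin, Slc26a4, at 9.17 TPM ± 2.01.

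Glomerular, vascular and stromal cells were represented as well. All 9 podocyte genes were at TPM 1 or more in both libraries, with Podxl at 23.1 TPM ± 1.39, podocin, Nphs2, at 8.18 TPM ± 0.240 and nephrin, Nphs1, at 3.36 TPM ± 0.120. All 9 endothelial genes were detected, led by Plvap at 52.3 TPM ± 13.6, Egfl7 at 45.7 TPM ± 7.83 and Emcn at 32.6 TPM ± 3.49. The podocyte list lay 1.01 below the endothelial list on the log2 scale, at -1.01 ± 0.06 (SD, n = 2), or 0.497-fold. Renin, Ren1, of juxtaglomerular cells stood at 17.6 TPM ± 0.233, the collagen gene Col3a1 at 11.8 TPM ± 1.03 and the macrophage receptor Csf1r at 9.72 TPM ± 2.23. Lymphocyte genes were near the limit of detection. Only Ighm, the heavy chain of IgM, at 2.38 TPM ± 0.0212, was at TPM 1 or more in both libraries among 8 genes.

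**Figure D1:**
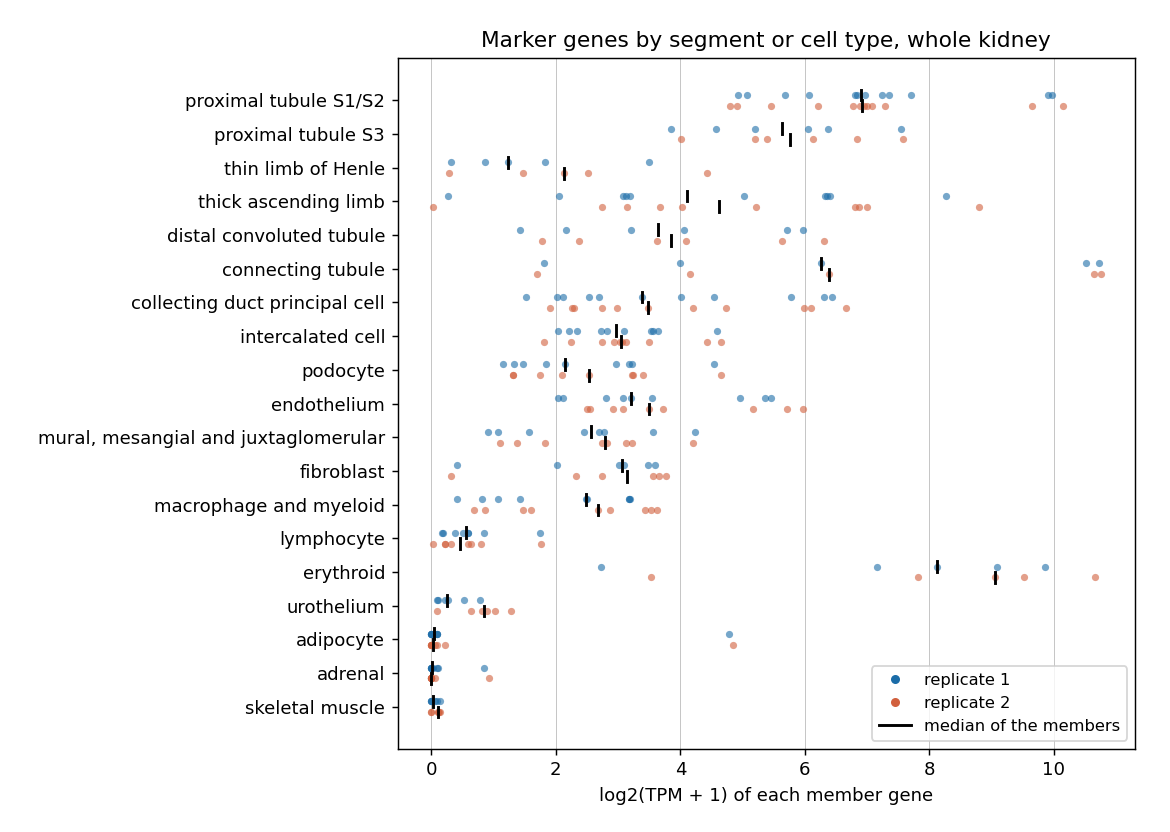
Level of each marker gene in each library, as log2(TPM + 1) on the horizontal axis, for 19 segment and cell type lists. Points are genes, colours are the replicates and black bars are the medians of the members; the bars of the S1 and S2 list and of the connecting tubule list lie to the right of those of the other epithelial lists, and those of adipocyte, adrenal and skeletal muscle lists lie near 0.

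Of other tissues, blood left the most reads, with all 5 erythroid genes detected and Hba-a2 at 1268 TPM ± 486. The alpha-globin genes are nearly identical, so the division between Hba-a1 and Hba-a2 is uncertain. Of 8 adipocyte genes only Fabp4, which endothelial cells also express, was above TPM 1, at 27.2 TPM ± 0.813, while Adipoq had 0 and 1 reads. Of 8 adrenal genes Star was highest at 0.850 TPM ± 0.0849, and Pnmt, Th, Dbh and Hsd3b1 had no read in either library. A count of 0 allows up to 3 reads, which for a gene of median length is 0.0833 TPM in replicate 1 and 0.0976 TPM in replicate 2. No gene of the skeletal muscle list exceeded 0.0900 TPM ± 0.0141, the mean of Tnni2. None of the 6 urothelial genes was at TPM 1 or more in both libraries. In the liver list Apoa2 stood at 9.90 TPM ± 2.41, Fga at 4.75 TPM ± 0.651 and Alb at 2.93 TPM ± 1.37.

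Genes of the Y chromosome were expressed and Xist was close to 0. Eif2s3y stood at 15.2 TPM ± 1.98, Ddx3y at 6.75 TPM ± 0.735, Uty at 4.86 TPM ± 0.799 and Kdm5d at 3.69 TPM ± 0.849, while Xist, expressed from the inactive X chromosome, had 5 and 7 reads, or 0.0250 TPM ± 0.00707. Among genes that are higher in the male proximal tubule, Cyp2e1 stood at 421 TPM ± 93.4 and Odc1 at 383 TPM ± 34.5, besides Kap. The female-biased genes Cyp4a14, Prlr and Slc7a12 stood at 14.9 TPM ± 6.18, 2.19 TPM ± 0.537 and 0.590 TPM ± 0.212. Of the circadian clock genes, 12 of 14 were at TPM 1 or more in both libraries. The output regulators Tef and Dbp were highest, at 80.5 TPM ± 8.69 and 49.0 TPM ± 2.45, followed by Hlf at 28.0 TPM ± 0.516 and Nr1d2 at 16.2 TPM ± 1.025, while Arntl and Npas2, of the activating limb of the clock, stood at 0.570 TPM ± 0.0849 and 0.395 TPM ± 0.219. Injury and growth genes were mostly low. Spp1 and Clu, which healthy tubules also express, stood at 279 TPM ± 46.8 and 82.1 TPM ± 0.375, whereas Havcr1, the injury marker KIM-1, stood at 0.510 TPM ± 0.0141 and Lcn2 at 2.85 TPM ± 1.22. None of the 6 proliferation genes was at TPM 1 or more in both libraries, and Mki67 stood at 0.470 TPM ± 0.0283.

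Metabolic and transport functions of the tubule were well represented. All 9 genes of gluconeogenesis and ammoniagenesis were detected, including Fbp1 at 586 TPM ± 82.9 and Pck1 at 405 TPM ± 95.6, both enzymes of gluconeogenesis. All 12 genes of fatty acid oxidation were detected, with Acadm at 370 TPM ± 77.3 and Acox1 at 209 TPM ± 19.0. Of 12 organic ion and drug transporters, 11 were at TPM 1 or more in both libraries, led by the urate transporter Slc22a12 at 476 TPM ± 45.9 and the efflux transporter Slc47a1 at 183 TPM ± 8.91. All 9 amino acid transport genes, led by Slc3a1 at 108 TPM ± 2.10, and all 18 subunits of the V-ATPase proton pump, led by Atp6v0c at 342 TPM ± 24.6, were detected. The lists of vitamin D and phosphate handling and of the renin-angiotensin system had 9 of 9 and 7 of 8 genes at TPM 1 or more in both libraries. The parathyroid hormone receptor gene Pth1r stood at 138 TPM ± 9.83, the Fgf23 coreceptor Kl at 67.3 TPM ± 3.67 and the angiotensin-converting enzyme gene Ace at 22.9 TPM ± 1.99. In the interferon response list 8 of 9 genes were at TPM 1 or more in both libraries, with Bst2 highest at 11.2 TPM ± 2.28.

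Related transporters, enzymes and receptors were compared within each library, where sequencing depth cancels. Of 24 pairs, 13 differed by more than 1.22 on the log2(TPM + 1) scale, which is 3 times the pooled SD of 0.41 between libraries over all genes at mean TPM 1 or more. The sodium pump isoform Atp1a1 exceeded Atp1a2 by 9.22 ± 0.06 (log2, SD, n = 2), the cytosolic Pck1 exceeded the mitochondrial Pck2 by 6.95 ± 0.13, and the phosphate transporter Slc34a1 exceeded Slc34a3 by 5.92 ± 0.17. Hnf4a exceeded its paralog Hnf4g by 5.87 ± 0.14, the kidney-type glutaminase Gls exceeded Gls2 by 5.07 ± 0.08, and the low-affinity glucose transporter Slc5a2 exceeded the high-affinity Slc5a1 by 3.20 ± 0.28. The 6 smallest differences stayed within that limit of 3 times the pooled SD. Some of them still exceeded the pooled SD itself, or their own SD. Slc7a9 and Slc7a7, which carry basic amino acids across the apical and the basolateral membrane, were at 41.8 TPM ± 7.04 and 41.6 TPM ± 8.89, a log2 ratio of 0.01 ± 0.06. Aqp2 over Aqp3 gave 0.34 ± 0.31, Slc22a1 over Slc22a2 -0.39 ± 0.26, Slc12a1 over Slc12a3 0.51 ± 0.23, Slc4a1 over Slc26a4 -0.70 ± 0.71 and Ace2 over Ace -0.79 ± 0.06. The number of pairs past this limit rose to 19 when the pooled SD was taken from nuclear protein-coding genes alone, a choice made after the data were examined.

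**Figure D2:**
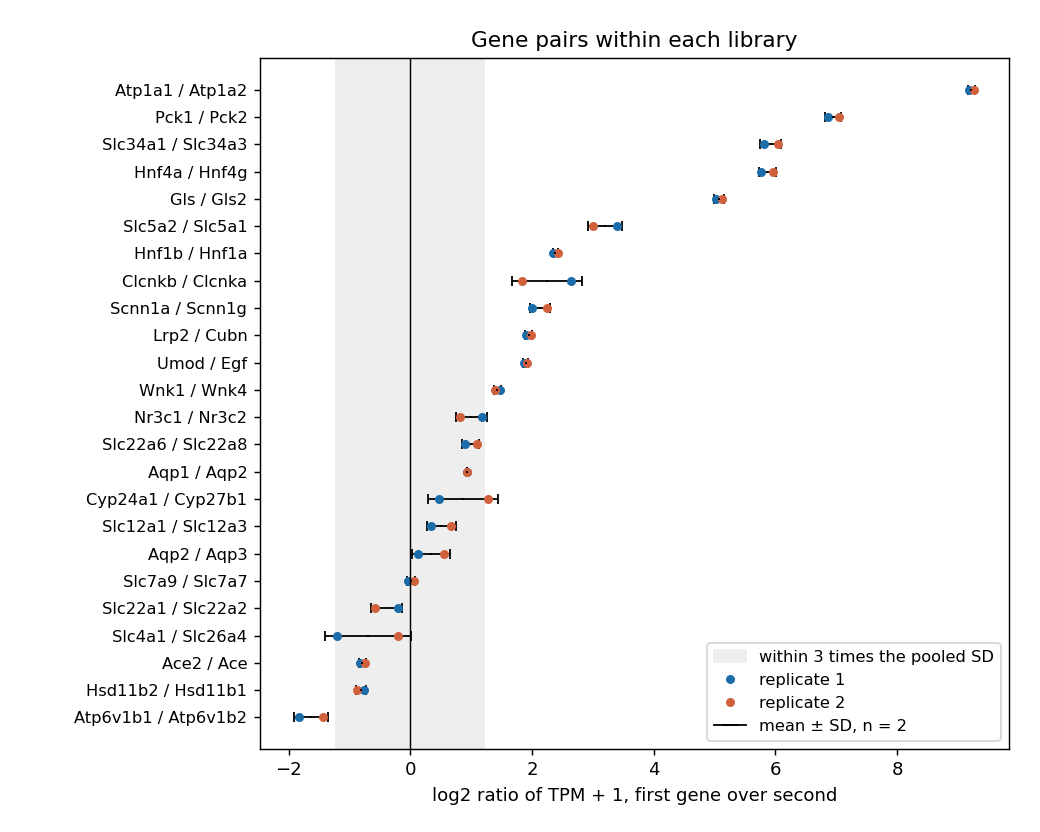
Log2 ratio of TPM + 1, first gene over second, for 24 gene pairs within each library. Points are replicates, bars are the mean ± SD (n = 2) and the grey band spans 3 times the pooled SD of 0.41; 13 pairs lie outside the band, from -1.63 for Atp6v1b1 over Atp6v1b2 to 9.22 for Atp1a1 over Atp1a2.

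Transcript tables allowed the leading annotated transcript, the one with the highest TPM, to be compared for 24 genes. The same transcript led in both libraries for 16 genes, and for 11 of the 19 genes with more than 1 annotated transcript. Lrp2-201 held 77.8% ± 4.13 of the TPM of Lrp2, Slc5a2-202 held 63.5% ± 1.38 of Slc5a2, Pth1r-202 held 69.6% ± 2.26 of Pth1r and Vdr-201, of the vitamin D receptor gene, held 84.6% ± 0.382. Bsg-201 held 46.1% ± 1.40 of Bsg, and Pkm-201 held 76.1% ± 14.4 of Pkm. The leading transcript changed for Slc12a1, Slc4a4, Wnk1, Tpm1, Enah, Fgfr2, Wt1 and Cd44. In Slc12a1, on chromosome 2 at 125152505 to 125230002, Slc12a1-201 held 44.1% and 29.8% in replicates 1 and 2, and Slc12a1-202 held 26.8% and 32.2%. In Slc4a4, Slc4a4-207 held 42.7% and 35.9% and Slc4a4-203 held 34.8% and 38.8%. Cd44 had a mean of only 0.310 TPM ± 0.0990, and its leading transcript rested on few reads. When the leading transcript was taken by expected counts in place of TPM, it was the same in both libraries for 20 genes. How reads shared by overlapping transcripts were divided is an estimate of the quantification, and no test was made.

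The libraries ranked genes alike. At TPM 1 or more, 13023 genes were detected in replicate 1, 13702 in replicate 2 and 12567 in both. Across 13349 genes with a mean TPM of 1 or more, which are not independent replicates, Spearman's rho was 0.968 and Pearson's r on log2(TPM + 1) was 0.976. Nuclear protein-coding genes were higher in replicate 2 by a median of 0.13 on the log2(TPM + 1) scale, and the mitochondrial share of gene reads was lower there. With that shift removed, 97.1% of 11322 nuclear protein-coding genes at mean TPM 1 or more lay within 1.5-fold and 99.7% within 2-fold. Both shares are for ratios of TPM + 1, which understate the change of low genes. The median coefficient of variation of TPM over these nuclear protein-coding genes was 10.4%. The common biological coefficient of variation, estimated by edgeR over 15237 genes, was 0.120. The counts differed by more than sampling noise, with a mean chi-square of 21.6 per gene, so these are not a single library deposited under 2 names. This mean weighs abundant genes most and is not the value of a typical gene. By the exact binomial test 4564 of the 15237 genes had an unadjusted p under 0.05.

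Among nuclear protein-coding genes with a mean TPM of 5 or more, 11 differed at least 2-fold between the libraries by the counting test, 6 higher in replicate 2 and 5 higher in replicate 1. These genes were chosen after their values were seen. Pdk4, which restrains glucose oxidation in fasting, stood at 2.93 TPM in replicate 1 and 8.71 TPM in replicate 2, a log2 ratio of 1.40 (counting SE 0.13, adjusted p = 1.79e-27, exact binomial test with Benjamini-Hochberg adjustment). Apoa4, an apolipoprotein gene, stood at 3.97 and 9.67 TPM, a log2 ratio of 1.12 (counting SE 0.16, adjusted p = 4.21e-11, exact binomial test), and Cish, a target of cytokine signalling, at 5.87 and 11.5 TPM, a log2 ratio of 1.00 (counting SE 0.10, adjusted p = 8.86e-23, exact binomial test). In the other direction Car3, carbonic anhydrase 3, stood at 12.03 and 3.20 TPM, a log2 ratio of -1.90 (counting SE 0.19, adjusted p = 1.62e-27, exact binomial test), and Cyp4a12a, a fatty acid hydroxylase of male kidney, at 31.6 and 11.4 TPM, a log2 ratio of -1.63 (counting SE 0.08, adjusted p = 2.11e-96, exact binomial test). Cyp4a12b, a close copy of Cyp4a12a, had 4.76 and 4.63 TPM. The other genes were Hsd17b14, Methig1 and Kcnt1, higher in replicate 2, and Apom, Ftl1-ps1 and Dynlt1a, higher in replicate 1. Expected counts of Methig1, Ftl1-ps1, Dynlt1a, Apoa4, Cish and Cyp4a12a were not whole, so their ratios depend in part on how shared reads were divided. Of the 11, Dynlt1a alone did not pass with an assumed biological coefficient of variation of 0.1 (adjusted p = 0.0602, edgeR's exactTest). The assumed value, here and below, is lower than the 0.120 estimated over all tested genes and the 0.108 over nuclear protein-coding genes. Calls near the threshold may therefore not hold at the estimated spread.

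Over all 15237 genes tested, 273 differed between the libraries at an adjusted p under the 0.05 threshold and a log2 ratio of 1 or more in size, 174 of them higher in replicate 2 and 99 higher in replicate 1. With total counts in place of TMM scaling the split was 288 higher in replicate 2 and 75 higher in replicate 1. Nuclear protein-coding genes made up 123 of the 273, and pseudogenes 78. The genes with the largest ratios at a mean TPM of 5 or more were mostly processed pseudogenes and small nuclear RNA copies, for which reads can be divided among near-identical sequences. Gm3150 had 0 reads in replicate 1 and 43.9 in replicate 2, while Gm3699 and Gm10736 each had 198 reads in replicate 1 and 0 in replicate 2, and Rpl9-ps7 had 232 and 9.48. The test holds counting error only and compares these libraries, not conditions. With an assumed biological coefficient of variation of 0.1 in edgeR's exactTest, 116 genes differed, 59 higher in replicate 2 and 57 higher in replicate 1, and 42 of them were nuclear protein-coding.

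Gene lists fixed beforehand were compared between the libraries through the median log2 ratio of their members, relative to the median of all nuclear protein-coding genes, and set against 10000 random lists matched on size and expression. Of 37 lists, 10 lay outside the central 95% of random lists, where 1.85 would do so by chance. These percentiles describe the 2 libraries, and genes regulated together leave the central range more often than random ones. Of the 278 list entries with enough reads to be tested, 3 were higher in replicate 2 and 1 was higher in replicate 1 by at least 2-fold and the adjusted p of the exact binomial test over all genes, and the same numbers resulted when p was adjusted over the list alone. At any ratio, 52 were higher and 82 lower in replicate 2 by that test, which holds counting error only. With an assumed biological coefficient of variation of 0.1 in edgeR's exactTest, 5 were higher and 3 lower in replicate 2 at any ratio.

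Lists of the loop of Henle lay higher in replicate 2. The thick ascending limb list lay 0.37 above all genes (percentile 100), with Slc12a1 at 78.8 TPM in replicate 1 and 126 TPM in replicate 2, Umod at 307 and 443 TPM, and Cldn19, a claudin of this segment, at 7.41 and 15.4 TPM. Of 10 members, 8 were higher in replicate 2 beyond the shift of all genes, and Enox1, at 12 and 1 reads, had too few to be tested. Of the 9 tested, 7 had an adjusted p under the threshold at any ratio, also when adjusted over the list alone. On TMM-scaled counts none of the 9 reached 2-fold. None passed with the assumed coefficient of 0.1. The thin limb list lay 0.56 above all genes (percentile 99.98), with Clcnka at 10.3 and 20.5 TPM, and Slc14a2, at 1.34 and 3.37 TPM, passed the 2-fold test (log2 ratio 1.17, counting SE 0.22, adjusted p = 1.13e-06, exact binomial test). The amino acid transport list lay -0.36 from all genes (percentile 0.0200), with Slc7a7 at 47.9 and 35.4 TPM and Slc7a8 at 31.9 and 25.5 TPM, although Slc6a18 stood at 82.7 and 108 TPM. The S1 and S2 list of the proximal tubule lay -0.18 from all genes (percentile 4.29), inside the central range, and all 12 members had an adjusted p under the threshold on TMM-scaled counts, towards replicate 1 and at less than 2-fold, and 1, Gatm, passed with the assumed coefficient of 0.1. On that scale its percentile was 0.570, outside that range.

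The fixed list of fasting genes, targets of the lipid-activated receptor PPAR-alpha, lay higher in replicate 2 as well. On TPM all 8 expressed members were higher there beyond the shift of all genes, at a median of 0.39 (percentile 100), while on TMM-scaled counts Plin2 was lower, at a log2 ratio of -0.107. By the exact binomial test 6 had an adjusted p under the threshold at any ratio, also when adjusted over the list alone, and with the assumed coefficient of 0.1 only Pdk4 and Hmgcs2 passed. Besides Pdk4, the ketogenic enzyme gene Hmgcs2 stood at 4.31 and 8.83 TPM, Cyp4a14 at 10.5 and 19.2 TPM, Cyp4a10 at 68.7 and 99.3 TPM and Angptl4 at 23.8 and 34.7 TPM. Cyp4a genes are close paralogs and share reads. The list of fatty acid oxidation enzymes lay -0.06 from all genes (percentile 55.7), and whether it differed from the fasting list was not tested.

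Blood, stress and mitochondrial genes also stood apart. All 5 erythroid genes were higher in replicate 2 by a median of 0.67 beyond all genes (percentile 100), with Hba-a1 at 276 and 532 TPM and Alas2, of haem synthesis, at 5.60 and 10.6 TPM. The immediate early and heat shock list lay 0.24 above all genes (percentile 99.85), with Jun at 2.65 and 5.72 TPM, Egr1 at 0.700 and 1.26 TPM and Hspa1a at 1.41 and 2.40 TPM, while Fos had 2 and 4 reads and Atf3 ran the other way with 14 and 5 reads. With a fit on GC content and length removed, an alternative chosen after the data were examined, its median was 0.14 (percentile 98.43), and with the assumed coefficient of 0.1 only Jun passed. The urothelial list lay 0.38 above all genes (percentile 99.97), but no member passed the test and the highest, Psca, had 6 and 17 reads. All 13 mitochondrial protein genes were lower in replicate 2, at a median of -0.43 from all nuclear genes (percentile 0). Among them mt-Co1 stood at 36913 and 29631 TPM and mt-Atp6 at 12591 and 8223 TPM. Only Kap and Gpx3 of the nuclear protein-coding genes exceeded the lowest of the 13. Most random members were therefore far less expressed, and the match on expression is loose for this list. With that fit removed the median of the 13 was -0.26 (percentile 0.03), and with the assumed coefficient of 0.1 only mt-Atp6 and mt-Atp8 passed. By that test 1 of the erythroid genes, Hba-a1, passed, and no member of the amino acid transport, urothelial, male-biased or intercalated cell lists did. The list of male-biased proximal tubule genes lay -0.32 from all genes (percentile 0.460), with Cyp2e1 at 488 and 355 TPM and Acsm3 in the opposite direction at 286 and 382 TPM, and the intercalated cell list lay -0.15 from all genes (percentile 1.96), with Slc26a4 at 10.6 and 7.75 TPM and Aqp6 in the opposite direction at 11.4 and 20.4 TPM. These last lists, male-biased and intercalated, fell inside the central range on the TMM scale, at percentiles of 2.92 and 2.52.

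**Figure D3:**
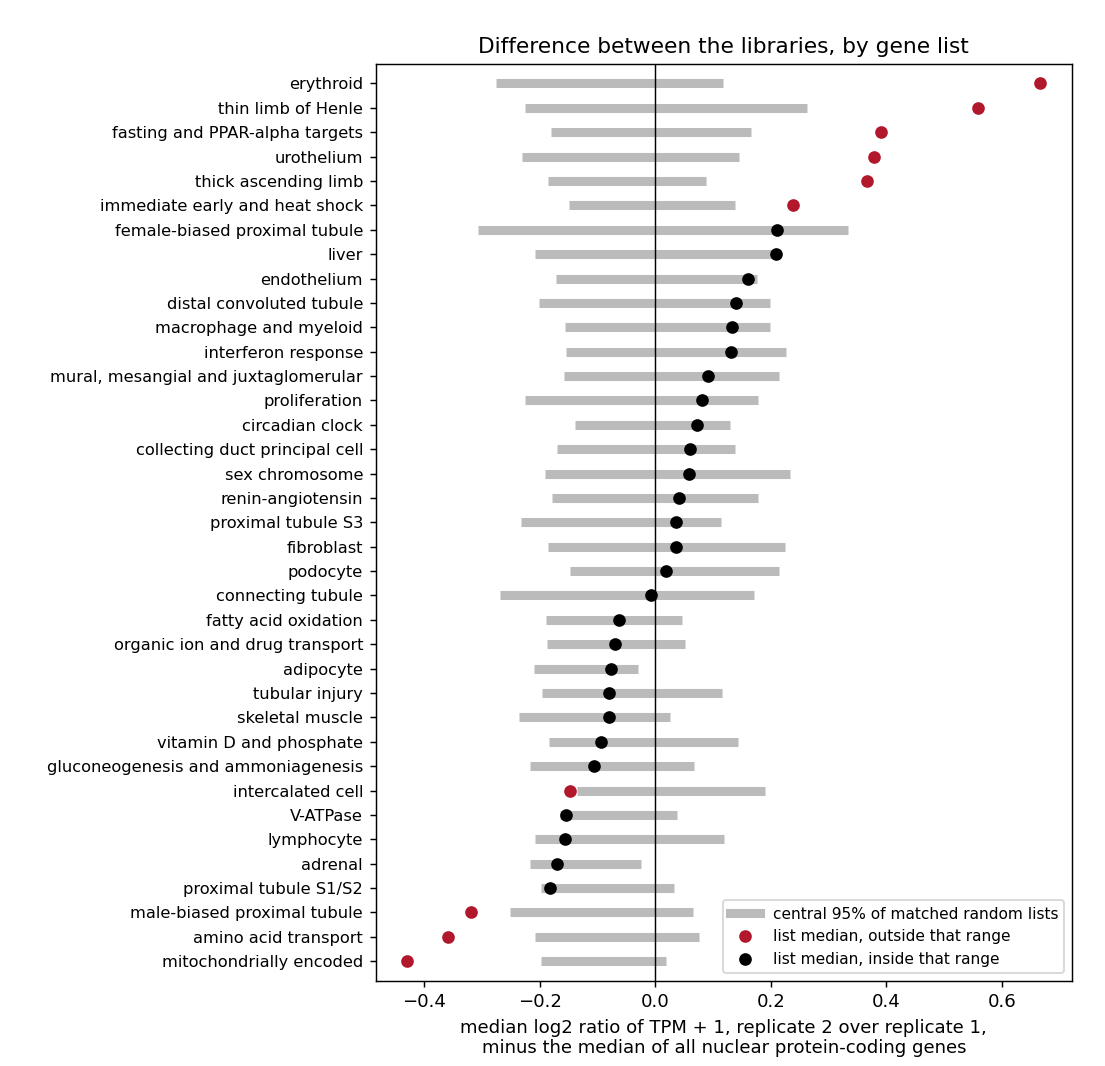
Median log2 ratio of TPM + 1, replicate 2 over replicate 1, of the members of each of 37 gene lists, minus the median of all nuclear protein-coding genes. Grey bars span the central 95% of 10000 random lists matched on size and expression; red points, 10 lists, lie outside their bar, from -0.43 for mitochondrially encoded genes to 0.67 for erythroid genes.

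The remaining 25 lists lay inside the central range, although the endothelial and liver lists left it once the fit on GC content and length was removed (percentiles 98.59 and 99.42). Among the 25 were the distal convoluted tubule (0.14 from all genes, percentile 92.9), connecting tubule (-0.01, percentile 68.7), principal cell (0.06, percentile 85.2), S3 segment (0.04, percentile 87.2), podocyte (0.02, percentile 47.3), endothelial (0.16, percentile 96.7), mural cell (0.09, percentile 76.7), fibroblast (0.03, percentile 57.5), macrophage (0.13, percentile 90.2) and lymphocyte lists (-0.16, percentile 8.54). The lists of neighbouring tissues were those of adipocyte (-0.08, percentile 80.7), adrenal (-0.17, percentile 14.7), skeletal muscle (-0.08, percentile 64.2) and liver genes (0.21, percentile 97.49). The sex chromosome list lay 0.06 from all genes (percentile 77.0), the female-biased list 0.21 (percentile 90.3), the circadian clock list 0.07 (percentile 88.1), the tubular injury list -0.08 (percentile 33.3), the proliferation list 0.08 (percentile 86.55) and the interferon list 0.13 (percentile 86.4). The functional lists of gluconeogenesis and ammoniagenesis (-0.11, percentile 33.5), organic ion and drug transport (-0.07, percentile 49.1), V-ATPase (-0.16, percentile 4.07), the renin-angiotensin system (0.04, percentile 65.4) and vitamin D and phosphate (-0.09, percentile 19.9) did so too. Within these lists Cdkn1a, of the injury list, was higher in replicate 2 at 2.24 and 5.10 TPM and Oas1a, of the interferon list, was higher in replicate 1 at 0.910 and 0.320 TPM, each at least 2-fold and past the exact binomial test. Neither passed with the assumed coefficient of 0.1 (adjusted p = 0.0595 for Cdkn1a and 0.166 for Oas1a, edgeR's exactTest), and Oas1a rests on 27.9 and 8.47 reads.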

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

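No test of outlying samples applies to a group of 2, and with 1 group there is no effect to compare between groups. What stood out lies in rows of the gene tables that the comparisons did not use, at more reads than a count of 0 allows. The labels name spike-in RNA, and the 96 ERCC spike-in rows together held 9 reads in replicate 1 and 8.99 reads in replicate 2, spread over 9 of the rows. The 26248 tRNA rows held 3305.52 reads in replicate 1 and 3810.38 reads in replicate 2, or 0.0194% and 0.0253% of all expected counts.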

How the results depend on the processing

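Counts were held to 1.5 times the main count and differences between lists to 1 SD. Correlations and the biological coefficient of variation have no spread to be held to, and every alternative value of theirs is given. Among the main results 34 alternative values lay within these limits, and the other 21, with some inside, follow. The 34 include list differences in single libraries, which lie within 1 SD of the mean of 2 libraries by construction. They also include list differences on FPKM, which is TPM times a factor per library, so these could hardly move. Of the alternative values of lists and genes, 114 kept their direction and call, 5 kept the direction alone and 0 reversed. Restriction to nuclear protein-coding genes, all-gene random lists, the GC and length fit, removal of shared members and the pooled SD from protein-coding genes were chosen after seeing the data. Where no cause is given below, the cause was not tested. Genes detected in both libraries numbered 7517 at a TPM of 5, a stricter limit, 18448 at a TPM of 0.1, a looser limit, 15038 on posterior mean TPM, and 13023 to 13702 in single libraries. Spearman's rho was 0.919 without a filter, 0.962 at a mean TPM of 5 or more, 0.968 on FPKM, 0.989 on expected counts and 0.984 over protein-coding genes, and Pearson's r was 0.947 with a pseudocount of 0.1. The biological coefficient of variation was 0.120 with DESeq2's size factors, 0.135 with total counts, 0.121 without a filter, 0.110 at 100 counts or more and 0.108 over protein-coding genes. Differing genes numbered 28 at 100 counts or more and 125 over protein-coding genes, where fewer genes were tested, 3004 with no minimum of the ratio, 75 at a log2 ratio of 2, and 116 with a fixed biological coefficient of variation of 0.1. The proximal tubule list exceeded the principal cell list by 3.58 with a pseudocount of 0.1 and by 3.13 on means of members, and the podocyte list lay -1.16 and -1.24 from the endothelial list under the same changes. In single libraries the proximal tubule list exceeded the thick ascending limb list by 2.29 to 2.79 and the principal cell list by 3.43 to 3.51, the podocyte list lay -1.05 to -0.97 from the endothelial list, and 13 to 14 pairs differed. Pairs that differed numbered 9 with a pseudocount of 0.1, and 19 on scaled expected counts and with the other pooled SD. Lists standing apart numbered 9 to 13; the urothelial list had too few members at a mean TPM of 1 or more for that alternative. The S1 and S2 list also stood apart on the TMM scale and with the GC and length fit removed, the endothelial list with that fit removed, and the liver list with it removed and without shared members. The calls that ended were those of the intercalated cell list on the TMM scale and without shared members, of the male-biased list on the TMM scale, and of Gm38208 and Snora78 with the fixed coefficient. At 36.0 and 30.7 reads per TPM, genes under a TPM of 1 rest on few reads. No paired analysis was possible because there was 1 group.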

Other observations

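The histone test below and the osmoprotective list were chosen only after related values had been seen. So were the comparisons with all genes for library size or composition in the thick ascending limb and fasting lists. Several genes of the osmoprotective list, which holds genes linked to the hypertonic medulla, were higher in replicate 2. The inositol transporter gene Slc5a3 stood at 12.6 TPM in replicate 1 and 23.2 TPM in replicate 2, the betaine transporter gene Slc6a12 at 0.440 and 1.86 TPM, the urea transporter gene Slc14a1 at 0.4 and 1.27 TPM, and the transcription factor gene Nfat5 at 14.4 and 20.7 TPM, while Akr1b3, aldose reductase, stood at 28.4 and 25.3 TPM. With Slc6a6, these 6 genes had a median 0.46 above all genes (percentile 99.98). Slc14a2 and Clcnka, of the thin limb list, moved the same way.

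Ratios of some single genes follow, none of which reached 2-fold on the TMM scale. On that scale Malat1, a nuclear long noncoding RNA, had a log2 ratio of 0.23 with 1.17% and 1.49% of gene reads, Neat1, of nuclear paraspeckles, had 0.40, and the small nuclear RNA Rn7sk had 0.56. The mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2 had log2 ratios of 0.02 and -0.05, and the 13 mitochondrial protein genes a median of -0.45, a difference that was not tested. On the TMM scale Txnip, a glucose-responsive gene, had a log2 ratio of 0.52, Hmgcr, of sterol synthesis, 0.64 and Mfsd2a, a lipid transporter gene, 0.94. The 8 single genes of this paragraph were chosen after their values were seen. With an assumed biological coefficient of variation of 0.1, edgeR's exactTest gave an adjusted p of 0.00412 for Mfsd2a, 0.169 for Hmgcr, 0.281 for Rn7sk, 0.388 for Txnip, 0.674 for Neat1, 0.975 for Malat1 and 1 for both rRNA genes, so that of these Mfsd2a alone passed. Of the 13 mitochondrial protein genes, 2 passed.

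The thick ascending limb list lay higher in replicate 2. GC content with transcript length was argued against as the whole cause, since the list stayed at percentile 100 after a fit on them was removed. Its level of 0.3668 above all genes (percentile 100) is the pattern itself, and a scaling factor shared by all genes nearly cancels in it. The percentile was also 100 on TMM-scaled counts, where such a factor nearly cancels too. Neither value therefore tests library size or composition. A larger share of medulla in replicate 2 may account for the higher list. A second list of 8 medulla and papilla genes reached percentile 80.35, between the bounds set beforehand. A larger share of medulla therefore cannot be told apart from a change within the segment. Within that list Cryab stood at 60.4 and 111 TPM and Slc4a11 at 1.33 and 3.75 TPM, but Ptgs1 at 7.57 and 7.92 TPM. The design names no biological difference between the replicates, and none was tested.

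The fixed list of fasting and PPAR-alpha targets lay higher in replicate 2. It stayed at percentile 100 with the GC and length fit removed, which argues against these as the whole cause. Its level of 0.3905 above all genes (percentile 100) is the pattern itself. A scaling factor shared by all genes nearly cancels there, and also on TMM-scaled counts (percentile 100). Neither value therefore tests library size or composition. Higher PPAR-alpha activity in the tissue of replicate 2 could be a candidate explanation, but a second list of targets, 9 of 10 expressed, reached percentile 95.17, between the bounds set beforehand for and against it. Cyp4a32 stood at 8.48 and 13.0 TPM, whereas Acaa1b stood at 88.0 and 85.8 TPM and Fabp3 at 66.0 and 67.9 TPM. No member of the second list was higher by the exact binomial test at any ratio, and Acaa1b was lower on TMM-scaled counts (adjusted p = 2.30e-05). The explanation remains open, and a difference between the animals, if they were different, cannot be separated from one in handling.

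Small nuclear and nucleolar RNAs were higher in replicate 2, in 100 of 129 genes. Their median log2 ratio on TMM-scaled counts was 0.3397 (95% bootstrap interval 0.25 to 0.44). A scaling factor shared by all genes nearly cancels on that scale, so this value does not test library size or composition. Less complete poly(A) selection may contribute, since 16 histone genes, most of which lack a poly(A) tail, had a median of 0.1986 (0.02 to 0.58). This interval is wide and its lower end is close to 0. Both bootstrap intervals are over genes, which are not independent replicates, and do not measure the spread between libraries. Over all 48 expressed histone genes, most of them low, the median on the log2(TPM + 1) scale lay 0.02 above all genes (percentile 98.69), so the support is weak. More unspliced nuclear RNA may contribute as well, since retained-intron transcripts held 4.27% of the reads of protein-coding genes in replicate 1 and 4.79% in replicate 2, a ratio of 1.121. Other RNA classes moved as well. On TMM-scaled counts the median log2 ratio was 0.48 for miRNA genes and 0.46 for rRNA genes, but -0.33 for mitochondrial tRNA genes. Whether the RNA size range named by the labels was kept alike in both libraries was not tested. The explanations above do not exclude each other or others, and no biological explanation was tested.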
